A study of Mus musculus with 9 samples.

How the data were processed

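The 9 libraries were RNA-seq libraries of total RNA, prepared with the CORALL V2 kit after extraction with RNAiso Plus, per the labels' protocols. The authors deposited whole-number counts per gene symbol, 1 table per library, with no normalization. The submitters' processing notes name fastp, STAR, Salmon, GATK and the mouse build GRCm39, without versions, roles or order. Whether molecular identifiers were collapsed, whether a quantifier's estimates were rounded, which gene annotation was used and whether counting used strand are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical copies are therefore uncertain, and counts of an introduced sequence cannot be told from those of the mouse gene.

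Groups and replicate numbers came from the sample titles. Library totals ran from 21149358 to 24786305 counts, and 12189 of the 40213 symbols had no count in any library. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16562, and libraries were scaled by TMM factors between 0.958 and 1.033. All 9 libraries entered 1 fit of 3 groups in edgeR 4.0.16 (R 4.3.3), with robust glmQLFit and glmQLFTest and Benjamini-Hochberg adjustment at 0.05. Fold changes are edgeR's, standard errors are the size of the log2 fold change divided by the square root of F, and CPM values use TMM-scaled library sizes unless stated. Pou5f1 and Ewsr1 were also compared by two-sided exact permutation tests.

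A total of 24 gene lists, the anchor genes and the rules below were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists of each comparison. All 11, 4 and 8 camera calls of the EWS-OCT4 versus OCT4, EWS-OCT4 versus J1 and OCT4 versus J1 comparisons were lost with an estimated correlation. The estimate was 0.486 for mitochondrial and 0.251 for glycolysis genes. It was -0.012 for ERK response, -0.04 for p53 target, -0.018 for naive, -0.019 for DNA methylation and -0.025 for Polycomb and chromatin genes, below the preset 0.01. Correlation above the preset is therefore not why these last calls were lost. For ERK response genes in EWS-OCT4 versus OCT4, the unadjusted camera p still rose from 3.21e-05 to 0.0042. For general pluripotency genes, whose estimate of 0.015 was close to the preset, it rose from 3.98e-05 to 0.00745. The setting thus changed more than the correlation, and a call lost under it is not by itself a sign of correlated members. The named genes were 12 anchors in each comparison, then the 6 largest changes per direction with adjusted p under 0.05, no overlap of the groups' values, a mean of at least 10 CPM in the higher group and a symbol that is not a predicted-gene name, then up to 2 members per direction of each described list with at least 5 CPM. Krt8 and Krt18 were named for a test written after the trophectoderm list result was known. Symbols were matched to GENCODE release M21 for chromosome, GC content and transcript length only, with 15065 of the 16562 tested genes matched; that release is on another build, so no coordinates are given. Chromosome medians used genes with a mean of at least 5 CPM, except the X-linked median weighed against cells with a second active X, which used all 567 tested X-linked genes.

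The tests were first run on simulated data. For EWS-OCT4 versus OCT4, 200 genes were changed among simulated counts, of which 16144 genes were tested. The fit recovered 22.4%, 54.2%, 74.0% and 95.8% of those changed 1.25-, 1.5-, 2- and 4-fold. These were 11, 26, 37 and 46 genes, beside 16 called among 15949 unchanged genes. A list raised 1.5-fold in simulated counts of the 16562 genes for the same comparison was called in 10 of 10 simulations, with 0 calls among the others. Genes were drawn independently there, so false calls from correlated members could not appear.

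The alternatives tried were RLE and upper-quartile scaling, no low-count filter, a minimum of 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the 6 libraries compared, the replicate number as a block, glmTreat against a fold of 1.5, each library left out in turn, and for lists an estimated correlation and fry. Alternatives without chromosomes 8, 11, X and Y, with chromosome 12 also left out, with a correction for GC content and transcript length, and without the 13 mitochondrial genes and Gm26917 were added after seeing the data. Where a gene is said to pass in some number of alternatives, glmTreat and the block are left out of that number. For the overlap of the 2 comparisons with J1, 20 pairs of unchanged groups were simulated around the mean of the J1 libraries. The J1 libraries' own error therefore did not enter these draws.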

Results

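Total RNA was sequenced in 9 libraries of mouse embryonic stem (ES) cells grown in medium with LIF, a cytokine that sustains their self-renewal. The control was J1, a widely used ES cell line, with 3 libraries. The other libraries came from stable lines that the labels call Niwa lines, 3 with OCT4 (the OCT4 line) and 3 with EWS-OCT4, a fusion of the RNA-binding protein EWS with OCT4 (the EWS-OCT4 line). OCT4, encoded by Pou5f1, is the transcription factor that holds ES cells in the pluripotent state. The stable lines received 1 µg/ml doxycycline, given to lower their endogenous OCT4, and the series asks whether the fusion can take over the role of OCT4 in self-renewal. Library totals ran from 21149358 to 24786305 counts, over 40213 gene symbols, of which 16562 had enough counts to be tested. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 3.36 and 32.0. The labels give each group 1 cell line name and do not say whether the numbered libraries of a stable line are repeats of 1 line or separately derived lines, nor whether J1 also received doxycycline. Construct and host line change together against J1, and any difference between clones is not separated from the construct.

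Counts of Pou5f1 were lower in both stable lines than in J1. J1 had 569 ± 61.8 CPM (counts scaled to library size; SD, n = 3), the OCT4 line 165 ± 2.61 and the EWS-OCT4 line 26.8 ± 2.12, which are 29.0% and 4.71% of J1. The log2 fold change was -1.79 (SE 0.081) for the OCT4 line and -4.41 (SE 0.0925) for the EWS-OCT4 line, with adjusted p = 2.9e-12 and 3.3e-16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test gave p = 0.1 for each pair of groups, the smallest value that 3 against 3 libraries allow. Reads of an introduced coding sequence may or may not be counted under the mouse gene, so these values do not measure the introduced proteins. Ewsr1, the mouse gene for EWS, had 560 ± 73.7 CPM in J1, 469 ± 45.5 in the OCT4 line and 531 ± 31.4 in the EWS-OCT4 line (SD, n = 3), with exact permutation p between 0.2 and 0.6.

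**Figure D1:**
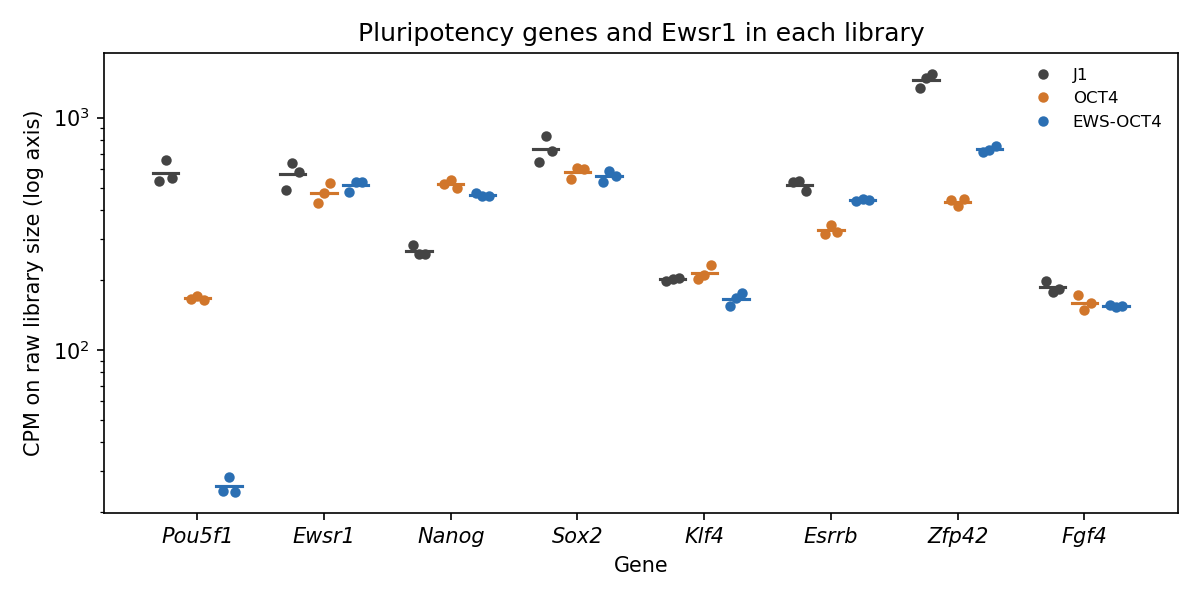
CPM on raw library sizes (log axis) of 8 genes in each of the 9 libraries; points are libraries, bars are group means. Pou5f1 lay between 24.5 and 28.3 CPM in the EWS-OCT4 libraries, between 164.7 and 171.3 in the OCT4 libraries and between 533.6 and 659.4 in the J1 libraries.

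The comparison of the EWS-OCT4 line with the OCT4 line sets the fusion against unfused OCT4 under the same doxycycline dose. These lines also differed in sex-linked expression. Relative to the autosomal median, the X-linked median differed by -0.519 (log2) and that of 4 Y-linked genes by 1.728. Any effect of that difference on the lists is not separated from the construct. In the EWS-OCT4 line, 16 of 20 general pluripotency and 14 of 17 ERK response genes were higher. There, 17 of 25 trophectoderm and 14 of 18 p53 target genes were lower. Pou5f1 and Klf4 were lower, and Nanog and Sox2 were not called. The camera calls of these 4 lists were lost in that order with adjusted p = 0.0894, 0.0894, 0.179 and 0.129 with an estimated correlation. Lefty1 and Lefty2, secreted inhibitors of Nodal signalling, were 24.6-fold and 23.9-fold higher, at 13.2 ± 0.879 and 58.6 ± 0.575 CPM against 0.535 ± 0.131 and 2.47 ± 0.748 (SD, n = 3). Hand1, a trophoblast transcription factor, stood at 2.14 ± 0.246 CPM against 78.2 ± 8.71 in the OCT4 line, and Gata6, a primitive endoderm factor, at 0.382 ± 0.275 against 9.34 ± 0.530. In all, 5282 genes were higher and 5730 lower in the EWS-OCT4 line (edgeR quasi-likelihood test, adjusted p under 0.05), of which 1414 and 2612 changed by at least 2-fold.

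Of the 20 general pluripotency genes, 16 were higher in the EWS-OCT4 line and 3 lower, the same counts as when adjusted over the list alone (camera, adjusted p = 0.000477; adjusted p = 0.0894 with an estimated correlation). Apart from Lefty1 and Lefty2, the examples were Pou5f1, lower by a log2 fold change of -2.62 (SE 0.0874), and Fbxo15, with -0.43 (SE 0.0669). Of the 17 ERK response genes, 14 were higher and 1 lower, over all genes and adjusted over the list alone (camera, adjusted p = 0.000477; adjusted p = 0.0894 with an estimated correlation). Egr1, an immediate early transcription factor, was higher by 3.22 (log2, SE 0.151) and Dusp6, a phosphatase that acts on ERK, by 1.89 (SE 0.0981), while Fos fell (-2.40, SE 0.145). Naive pluripotency genes went both ways, with 10 of 20 higher and 5 lower, also adjusted over the list alone (camera, adjusted p = 0.0467; adjusted p = 0.172 with an estimated correlation). Nr0b1 was 5.73-fold and Dppa3 5.45-fold higher, whereas Spic (log2 fold change -1.92, SE 0.170) and Tbx3 (-0.38, SE 0.0766) were lower. Esrrb (0.50, SE 0.0643) and Zfp42 (0.82, SE 0.0739) were higher and Klf4 (-0.30, SE 0.0722) lower in the edgeR quasi-likelihood test, with adjusted p = 2.19e-06, 2.89e-08 and 0.00135. Nanog (-0.08, SE 0.0653), Sox2 (0.01, SE 0.0851), Fgf4 (0.02, SE 0.0718) and Ewsr1 (0.18, SE 0.0932) did not pass that test, with adjusted p = 0.277, 0.911, 0.786 and 0.0979. Ewsr1 passed in 6 of 18 alternatives, with only the 6 libraries compared (adjusted p = 0.00802), no low-count filter (0.0143), the correction for GC content and transcript length (0.00341), or without EWS-OCT4 replicate 1 (0.0478), J1 replicate 1 (0.0182) or OCT4 replicate 3 (0.04), over a range up to 0.342. Nanog passed with the GC and length correction (0.0113), over a range up to 0.581.

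Of the 25 trophectoderm genes, 17 were lower in the EWS-OCT4 line and 4 higher, over all genes and adjusted over the list alone (camera, adjusted p = 0.0105; adjusted p = 0.179 with an estimated correlation). Besides Hand1, Esx1 fell by 4.53 on the log2 scale (SE 0.160) and Cdx2, a master regulator of trophectoderm, by 2.23 (SE 0.207), while Id2 (1.27, SE 0.120) and Krt7 (0.61, SE 0.155) rose. X-linked genes as a whole were lower in the EWS-OCT4 line, with a median log2 fold change of -0.45, and 4 of the 25 trophectoderm genes are X-linked. Of 18 p53 target genes, 14 were lower and 2 higher, also adjusted over the list alone (camera, adjusted p = 0.0131; adjusted p = 0.129 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell by 2.14 (log2, SE 0.086) and Btg2 by 1.90 (SE 0.0708), while Perp rose by 2.12 (SE 0.0968) and Tigar by 0.67 (SE 0.0714).

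Further lists passed camera in this comparison, each with the same counts when adjusted over the list alone unless stated. Of 18 formative genes, 12 were higher and 5 lower (camera, adjusted p = 0.0328; adjusted p = 0.341 with an estimated correlation), among them Foxp1 (2.40, SE 0.0949) and Zic2 (1.65, SE 0.101) upward and Otx2 (-1.80, SE 0.098) and Sox4 (-1.39, SE 0.107) downward. Of 12 neuroectoderm genes, 8 were higher and 3 lower (adjusted p = 0.0467; adjusted p = 0.341 with an estimated correlation), led by the eye and neural factor Pax6 at 10.5 ± 0.414 CPM against 0.455 ± 0.136. Msi1 (-1.78, SE 0.114) and Map2 (-1.59, SE 0.105) fell. Of 13 genes encoded by mitochondrial DNA, 8 were higher and 0 lower (adjusted p = 0.0211; adjusted p = 0.368 with an estimated correlation), and their share of all counts was 16.7% ± 0.411 in the EWS-OCT4 line, 11.5% ± 1.253 in the OCT4 line and 14.3% ± 1.61 in J1 (SD, n = 3). Gm26917, an abundant predicted gene, took 4.43% ± 1.19 of all counts in the OCT4 line, with 5.81% in OCT4 replicate 2, against 1.75% ± 0.101 in the EWS-OCT4 line and 0.963% ± 0.143 in J1. Of 12 DNA methylation genes, 8 were higher and 3 lower (adjusted p = 0.0467; adjusted p = 0.172 with an estimated correlation), with Dnmt3l (1.32, SE 0.0697) upward and Tet3 (-1.64, SE 0.126) and Dnmt3a (-0.93, SE 0.0655) downward. Of 20 Polycomb and chromatin genes, 12 were higher and 1 lower, or 12 and 2 adjusted over the list alone (adjusted p = 0.0328; adjusted p = 0.148 with an estimated correlation), with Eed (1.35, SE 0.0675) upward and Ezh1 (-0.78, SE 0.0807) downward. Of the 5 sex chromosome genes, 4 were higher and 1 lower (adjusted p = 0.0191; adjusted p = 0.148 with an estimated correlation).

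The other 13 lists did not pass camera in this comparison, with adjusted p from 0.0624 to 0.689. Their counts were the same adjusted over the list alone, except 11 imprinted genes higher. The cell cycle list, at 0.0624 (adjusted p = 0.341 with an estimated correlation), passed without EWS-OCT4 replicate 1 (0.0442), EWS-OCT4 replicate 2 (0.0496) or J1 replicate 3 (0.0452), without genes of chromosomes 8, 11, X and Y (0.0447), and with chromosome 12 also left out (0.0202). The germline list, at 0.0921, passed with the GC and length correction (0.0349), and had adjusted p = 0.341 with an estimated correlation. Higher and lower members numbered 8 and 3 of 15 OCT4-SOX2 enhancer targets, 5 and 10 of 19 primitive endoderm genes, 4 and 5 of 14 mesendoderm genes, and 6 and 3 of 14 two-cell-like genes. They numbered 4 and 6 of 13 fibroblast genes, 2 and 8 of 18 germline genes, 10 and 6 of 21 imprinted genes, 4 and 8 of 15 LIF response genes, and 12 and 4 of 24 cell cycle genes. They numbered 2 and 11 of 19 integrated stress response genes, 9 and 8 of 20 glycolysis genes, 6 and 4 of 11 interferon response genes, and 9 and 6 of 17 genes linked to the EWSR1-FLI1 fusion of Ewing sarcoma. The median and mean had opposite signs for the fibroblast, imprinted, glycolysis and interferon lists, and camera took the sign of the mean for glycolysis and of the median for the others. Among single genes, the largest increases also included Creb5 (6.64, SE 0.126), Ms4a14 (4.93, SE 0.176) and Enox1 (4.49, SE 0.124), and the largest decreases Bhmt (-6.35, SE 0.191), Vnn1 (-6.26, SE 0.257), Tnnt3 (-5.47, SE 0.315), Capn6 (-5.28, SE 0.216) and Cidea (-5.17, SE 0.262). Without genes of chromosomes 8, 11, X and Y the trophectoderm, formative, naive and DNA methylation calls were lost, with adjusted p = 0.109, 0.109, 0.443 and 0.0671, and with chromosome 12 also left out the trophectoderm, naive and neuroectoderm calls, with 0.0518, 0.938 and 0.0679, these and the GC and mitochondrial alternatives being chosen after seeing the data. The naive, neuroectoderm and DNA methylation calls were also lost with RLE scaling (adjusted p = 0.05, 0.0524 and 0.05), without mitochondrial genes and Gm26917 (0.0517, 0.0551 and 0.0517) and without J1 replicate 1 or OCT4 replicate 1 (up to 0.0637), and the naive and neuroectoderm calls with the GC and length correction (0.0571 and 0.0528) and without J1 replicate 2 (0.0597).

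The comparison of the EWS-OCT4 line with the J1 control asks how far cells carrying the fusion resemble unmodified ES cells. In the EWS-OCT4 line 13 of 14 two-cell-like and 16 of 25 trophectoderm genes were higher and 15 of 20 glycolysis genes lower. The camera calls of these 3 lists were lost in that order with adjusted p = 0.138, 0.242 and 0.29 with an estimated correlation. Nanog was 1.84-fold higher, at 481 ± 5.26 against 261 ± 13.8 CPM (SD, n = 3), whereas Zfp42, a marker of naive pluripotency, stood at 758 ± 27.4 against 1425 ± 114 CPM. Here 5016 genes were higher and 5233 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 1341 and 2062 changed by at least 2-fold.

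Of 14 two-cell-like genes, which mark a rare ES cell state resembling the early embryo, 13 were higher than in J1 and 0 lower, over all genes and adjusted over the list alone (camera, adjusted p = 1.78e-06; adjusted p = 0.138 with an estimated correlation). Zscan4d stood at 13.6 ± 0.857 against 1.68 ± 0.423 CPM in J1. Its transcript shares 65.0% of its 31-base sequence words with other genes, so its counts are uncertain, as are those of other members with near-identical copies. Of 25 trophectoderm genes, 16 were higher and 4 lower, or 17 and 4 adjusted over the list alone (camera, adjusted p = 0.00105; adjusted p = 0.242 with an estimated correlation). Rhox6 rose by 2.86 (log2, SE 0.141) and Rhox9 by 2.54 (SE 0.173), whereas Esx1 (-2.34, SE 0.169) and Tspan8 (-1.17, SE 0.214) fell. Cdx2 had 115 counts over the 3 EWS-OCT4 libraries and 4 over the J1 libraries. Of 20 glycolysis genes, 15 were lower and 2 higher, also adjusted over the list alone (camera, adjusted p = 0.0017; adjusted p = 0.29 with an estimated correlation), with Egln3 (-2.04, SE 0.111) and Pfkp (-1.46, SE 0.0632) downward and Hk2 (0.70, SE 0.0797) upward. Of 15 LIF response genes, 10 were higher and 3 lower, also adjusted over the list alone (camera, adjusted p = 0.0494; adjusted p = 0.242 with an estimated correlation). That call was lost when any 1 of the 9 libraries was left out, with adjusted p from 0.0506 to 0.0994. Tfcp2l1, a naive pluripotency factor in that list, was 2.85-fold higher at 660 ± 31.2 CPM, and Gbx2 rose by 2.52 (SE 0.096). Ier3 (-0.46, SE 0.126) and Socs3 (-0.22, SE 0.0705) fell. The Socs3 call was lost without EWS-OCT4 replicate 1 or 3 (adjusted p up to 0.0811).

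General pluripotency genes numbered 11 higher and 5 lower of 20, with camera adjusted p = 0.141, and naive genes 9 higher and 5 lower of 20, with adjusted p = 0.176, in both cases the same adjusted over the list alone. The median and mean differed in sign for the germline and ERK response lists, where camera took the sign of the median without a call. Gdf3 (1.70, SE 0.0903), Foxd3 (1.32, SE 0.109) and Klf5 (1.61, SE 0.129) rose, and Lefty1 (-1.32, SE 0.0941) and Klf2 (-0.69, SE 0.0691) fell. Sox2 (-0.30, SE 0.0851), Klf4 (-0.20, SE 0.0721) and Fgf4 (-0.19, SE 0.0716) were lower by the edgeR quasi-likelihood test, with adjusted p = 0.00497, 0.0245 and 0.0288. Esrrb (-0.14, SE 0.064) and Ewsr1 (-0.08, SE 0.0931) did not pass that edgeR test, with adjusted p = 0.0727 and 0.495. Esrrb passed in 5 of 19 alternatives, with upper-quartile scaling (adjusted p = 0.0199), a minimum of 5 CPM (0.0184), DESeq2 (0.0441), without J1 replicate 3 (0.0461) and, chosen after seeing the data, without genes of chromosomes 8, 11, X and Y (0.0149), over a range up to 0.599. Ewsr1 passed without J1 replicate 1 (0.0407), over a range up to 0.978. Gata6 fell by 2.23 (SE 0.420), and Sox17, an endoderm factor, had 4 counts over the EWS-OCT4 libraries and 48 over the J1 libraries. Formative genes numbered 6 higher and 7 lower of 18 (camera, adjusted p = 0.519), also adjusted over the list alone, with Otx2 (-3.13, SE 0.0963) and Lef1 (-3.28, SE 0.234) downward. Pou3f1 (1.05, SE 0.135) and Pim2 (1.002, SE 0.091) rose. The largest increases were Mid1 (9.37, SE 0.149), Igf2 (6.72, SE 0.159), Creb5 (5.36, SE 0.109), Fkbp6 (5.05, SE 0.184), Sox21 (4.96, SE 0.112) and Erdr1x (4.96, SE 1.02), the last with an uneven 11.8 ± 15.3 CPM in J1. The largest decreases besides Pou5f1 were Abcc8 (-5.82, SE 0.262), Cubn (-5.16, SE 0.204), Acan (-4.26, SE 0.119), Meioc (-3.66, SE 0.117) and Rps15a-ps5 (-3.62, SE 0.237). The Klf4 call was lost without EWS-OCT4 replicate 1 (adjusted p = 0.174), EWS-OCT4 replicate 2 (0.0777) or J1 replicate 3 (0.0746) or with the GC and length correction (0.0922), which was chosen after seeing the data. The Fgf4 call was lost without any EWS-OCT4 replicate or without J1 replicate 1 or 3, with adjusted p from 0.0583 to 0.107, and with the GC and length correction (0.0637).

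The comparison of the OCT4 line with the J1 control gives the difference that a line with unfused OCT4 also shows. In the OCT4 line 18 of 25 trophectoderm genes were higher, and 15 of 20 general pluripotency, 13 of 18 formative and 13 of 17 ERK response genes were lower. The camera calls of these 4 lists were lost in that order with adjusted p = 0.0653, 0.0653, 0.229 and 0.0653 with an estimated correlation. Gata3, which drives trophectoderm genes, stood at 19.8 ± 1.95 CPM against 0.183 ± 0.0996 in J1 (SD, n = 3). Lefty1 fell by 5.94 (log2, SE 0.151) and Lefty2 by 5.36 (SE 0.123), while Nanog was 1.95-fold higher at 509 ± 18.5 CPM. Here 5674 genes were higher and 5424 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 2487 and 1902 changed by at least 2-fold.

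Of 25 trophectoderm genes, 18 were higher and 3 lower, over all genes and adjusted over the list alone (camera, adjusted p = 1.74e-05; adjusted p = 0.0653 with an estimated correlation). Cdx2 had 539 counts over the 3 OCT4 libraries and 4 over the J1 libraries, and Tspan8 (-3.48, SE 0.274) and Cdh3 (-0.69, SE 0.0794) fell. The X-linked median was 0.63 higher (log2) in the OCT4 line, and 4 of the 25 genes are X-linked. Of 14 two-cell-like genes, 13 were higher and 0 lower, also adjusted over the list alone (camera, adjusted p = 0.0001; adjusted p = 0.0653 with an estimated correlation), with Usp17la at 5.64 ± 0.361 against 0.575 ± 0.182 CPM. Of 18 p53 target genes, 13 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.00258; adjusted p = 0.0653 with an estimated correlation), with Btg2 up by 1.77 (SE 0.0703) and Cdkn1a by 1.45 (SE 0.0827). Perp (-0.75, SE 0.101) and Tigar (-0.23, SE 0.0719) fell. Of 15 LIF response genes, 10 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.0128; adjusted p = 0.0848 with an estimated correlation), with Pim1 up by 1.82 (SE 0.0747) and Icam1 by 1.70 (SE 0.0629). Il6st (-0.31, SE 0.0691) and Gbx2 (-0.30, SE 0.114) fell. Gbx2 was called in 13 of 20 alternatives, with adjusted p from 0.0106 to 0.0943. Its call was lost without J1 replicate 1 or OCT4 replicate 2 or 3. It was also lost with DESeq2 (adjusted p = 0.0614), limma-voom (0.0564), no low-count filter (0.054) and only the 6 libraries compared (0.0784).

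Of 20 general pluripotency genes, 15 were lower and 2 higher, also adjusted over the list alone (camera, adjusted p = 0.0018; adjusted p = 0.0653 with an estimated correlation). The 2 that rose were Fbxo15 (1.17, SE 0.0681) and Dppa2 (0.47, SE 0.0711). Of 18 formative genes, 13 were lower and 1 higher, also adjusted over the list alone (camera, adjusted p = 0.000772; adjusted p = 0.229 with an estimated correlation), with Lef1 (-4.84, SE 0.283) and Foxp1 (-2.12, SE 0.0948) downward and Pim2 (0.30, SE 0.0938) upward. Of 17 ERK response genes, 13 were lower and 2 higher, or 13 and 3 adjusted over the list alone (camera, adjusted p = 0.00541; adjusted p = 0.0653 with an estimated correlation). Egr1 fell by 4.08 (SE 0.147) and Spry4, a feedback inhibitor of the pathway, by 2.43 (SE 0.0741), while Fos (1.76, SE 0.135) and Etv1 (1.71, SE 0.076) rose. Of 20 glycolysis genes, 12 were lower and 4 higher, or 12 and 5 adjusted over the list alone (camera, adjusted p = 0.0381; adjusted p = 0.497 with an estimated correlation), with Slc16a3 (-1.99, SE 0.130) and Pdk1 (-1.85, SE 0.076) downward. Hk1 (1.47, SE 0.0917) and Hk2 (0.26, SE 0.0795) rose. Naive genes went both ways, with 11 lower and 7 higher of 20 (camera, adjusted p = 0.437), also adjusted over the list alone. Zfp42 (-1.73, SE 0.0754), Esrrb (-0.64, SE 0.0644) and Sox2 (-0.32, SE 0.0851) fell and Tfcp2l1 rose (1.55, SE 0.0739), while Klf4 did not pass the edgeR quasi-likelihood test (0.10, SE 0.072, adjusted p = 0.211).

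Gata6 rose by 2.40 (SE 0.270), and Sox17 had 9 counts over the OCT4 libraries and 48 over the J1 libraries. Fgf4 fell by 0.21 (SE 0.0717) and Ewsr1 fell by 0.26 (SE 0.0932, adjusted p = 0.0221 in the edgeR quasi-likelihood test). Fgf5, a marker of primed cells, was too low to be tested, with 19 counts over the J1 libraries and 3 over each stable line's libraries. The largest increases were Igf2 (9.23, SE 0.159), an imprinted growth factor gene, and Mid1 (8.81, SE 0.147), followed by genes close to 0 in J1. Over the 3 libraries of each group, Tnnt3 had 769 counts against 7 in J1, Gata3 1341 against 13, Vnn1 797 against 8, and Xist, the RNA that silences an X chromosome, 811 against 13. The largest decreases besides the Lefty genes were Ms4a14 (-5.08, SE 0.174), Gap43 (-5.00, SE 0.180), Enox1 (-4.56, SE 0.124) and Ncan (-4.51, SE 0.162). The Ewsr1 call was lost without J1 replicate 2 or 3 or OCT4 replicate 1 or 2, with adjusted p from 0.0549 to 0.12, the Fgf4, Pim2 and Hk2 calls without OCT4 replicate 2 (adjusted p = 0.0933, 0.0603 and 0.056), and the Tigar call without OCT4 replicate 1 (0.0641). The LIF response call was lost without J1 replicate 2 (adjusted p = 0.0557), and the glycolysis call without J1 replicate 2 or OCT4 replicate 1, with adjusted p up to 0.0757.

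**Figure D2:**
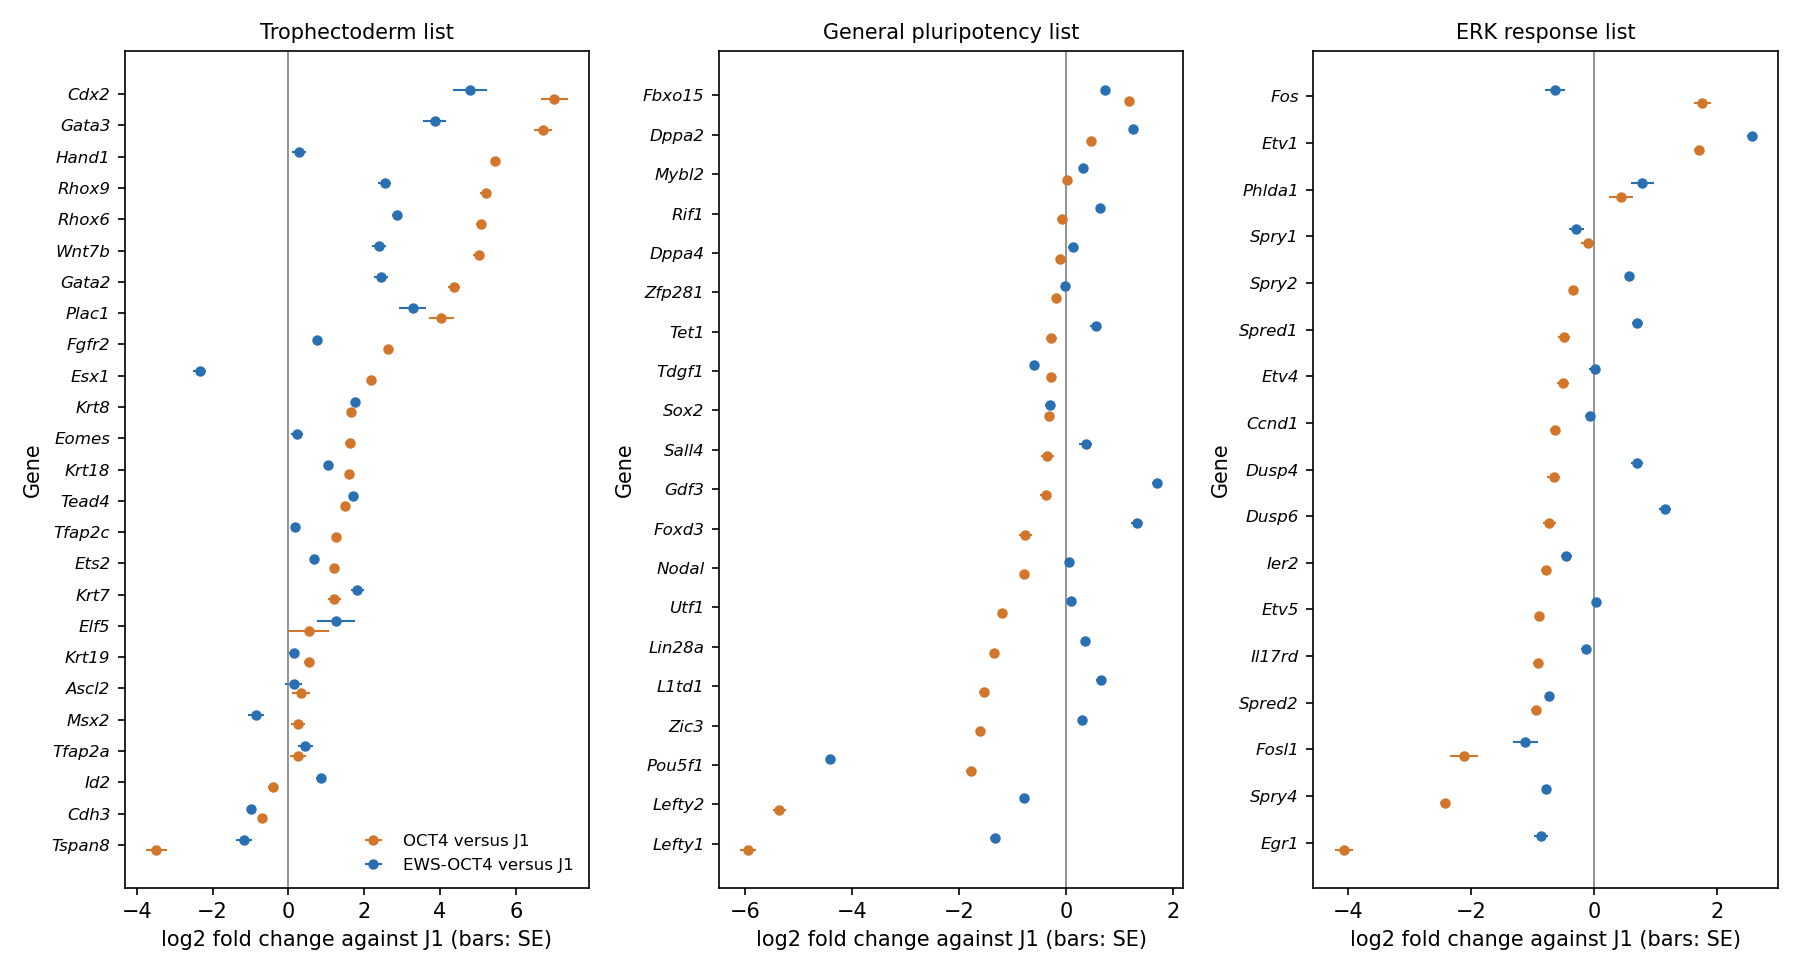
Log2 fold change against J1 (bars: SE) of the tested members of 3 gene lists in the OCT4 line and the EWS-OCT4 line. In the trophectoderm list 18 of 25 genes were higher than J1 in the OCT4 line and 16 in the EWS-OCT4 line; in the general pluripotency list 15 of 20 were lower in the OCT4 line and 5 in the EWS-OCT4 line.

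The genes called against J1 overlapped between the stable lines. Both were higher than J1 for 2713 genes and both lower for 2955, where independent lists of the same sizes would share 1718 and 1714. The 2 comparisons went opposite ways for 1752 genes, for which the count that independent lists would give was not computed. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.52, and the covariance was 0.701. In 20 simulated pairs of unchanged groups set against the same J1 libraries, the means were 0.13 and 0.0072. Those groups were drawn around the mean of these J1 libraries, so the error of the J1 libraries, which both comparisons share, did not enter. The simulation therefore cannot say how much correlation the shared J1 libraries give. The 3 controls cannot be split into groups of at least 2, so part of the overlap and of the correlation may come from the shared J1 libraries. The median absolute log2 fold change from J1 was 0.54 in the OCT4 line and 0.45 in the EWS-OCT4 line.

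Expression also differed by chromosome, which was examined after the gene results had been seen. Genes of chromosome 8 differed from the autosomal median by -0.46 (log2) in both stable lines against J1, and those of chromosome 11 by -0.46 in the OCT4 line and -0.51 in the EWS-OCT4 line. Between the stable lines, chromosomes 8 and 11 differed from the autosomal median by 0.01 and -0.04, and the largest autosomal difference there was -0.126 for chromosome 1 (95% bootstrap interval -0.184 to -0.073). Chromosome 1 differed by -0.168 (-0.199 to -0.136) in the EWS-OCT4 line and by -0.026 (-0.067 to 0.021) in the OCT4 line against J1. Genes of chromosome 12 differed from the autosomal median by -0.33 in the EWS-OCT4 line and -0.21 in the OCT4 line against J1, with J1 replicate 2 nearer to the stable lines. Centred on the mean of all libraries, chromosome 12 lay above the autosomal median by 0.11 in that library and by 0.23 and 0.21 in the other J1 libraries. X-linked genes were 0.66 above the autosomal median in the OCT4 line against J1 and 0.12 above it in the EWS-OCT4 line. The Y-linked genes Eif2s3y, Ddx3y and Uty stood at 56.1 ± 1.89, 48.0 ± 1.86 and 13.9 ± 0.676 CPM in the OCT4 line, against 243 ± 5.20, 132 ± 9.73 and 51.0 ± 9.15 in J1 and 188 ± 4.10, 172 ± 4.14 and 56.7 ± 3.48 in the EWS-OCT4 line (SD, n = 3). Uba1y, a further Y-linked gene named after its values were seen, stood at 3.44 ± 0.242 CPM in the OCT4 line, 36.8 ± 5.62 in J1 and 9.40 ± 1.246 in the EWS-OCT4 line, where it was lower than in J1 by a log2 fold change of -1.97 (SE 0.119; edgeR quasi-likelihood test, adjusted p = 2.43e-10). Xist stood at 12.01 ± 0.640 CPM in the OCT4 line, 5.22 ± 0.782 in the EWS-OCT4 line and 0.178 ± 0.123 in J1.

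**Figure D3:**
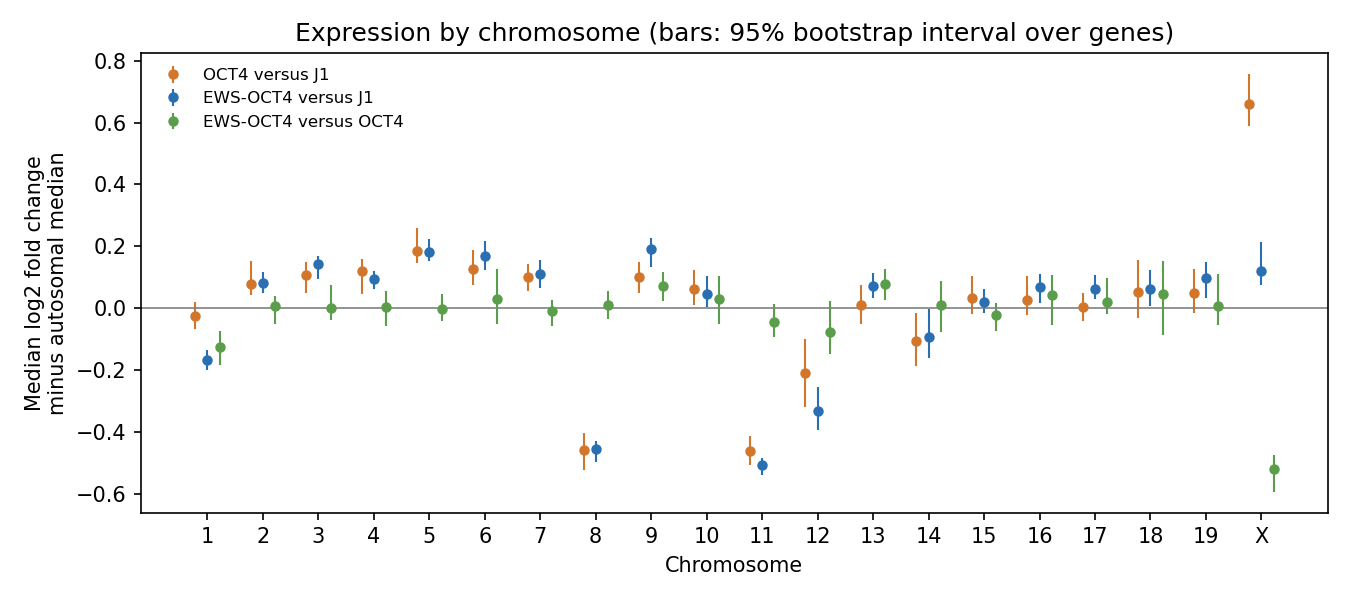
Median log2 fold change of each chromosome's genes minus the autosomal median, for the 3 comparisons; bars are 95% bootstrap intervals over genes. Chromosomes 8 and 11 lie near -0.46 to -0.51 in both comparisons with J1, chromosome 12 at -0.33 and -0.21, and the X chromosome at 0.66 in the OCT4 line against J1.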

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

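The difference between the stable lines' effects against J1 was tested by the contrast of the lines, and the tests of the Y-linked genes as a set, of the GC and length correction and of the counts taken by mitochondrial genes and Gm26917 were chosen only after the results were seen. Genes called in opposite directions against J1, and also different between the stable lines, numbered 845 that were higher in the EWS-OCT4 line and lower in the OCT4 line, and 907 with the reverse. These counts were not set against those that independent lists would give. Gata6 was 1 of the genes lower in the EWS-OCT4 line and higher in the OCT4 line, with a difference of -4.63 (log2) between the lines. Camera called 11 lists between the lines, and none of these calls held with an estimated correlation, where the lowest adjusted p was 0.0894. The median log2 difference, EWS-OCT4 minus OCT4, was 0.26 for naive pluripotency, 0.81 for general pluripotency, 0.80 for formative, -0.76 for trophectoderm, 1.05 for neuroectoderm and 0.86 for ERK response genes. It was -0.72 for p53 targets, 0.68 for mitochondrial, 0.58 for DNA methylation, 0.29 for Polycomb and chromatin and 1.84 for sex chromosome genes.

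The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real splits gave 11012, 10249 and 11098 genes for EWS-OCT4 versus OCT4, EWS-OCT4 versus J1 and OCT4 versus J1, and the highest other splits gave 0, 0 and 1, so 1 of the 10 splits reached the real count in each. Every other split mixes libraries of both groups, which puts the difference between groups into the spread within them. Their near absence of called genes follows from that and cannot serve as a measure of what unrelated libraries would give. For lists the real splits gave 11, 4 and 8 and the highest others 4, 4 and 7, with 1, 2 and 1 of the 10 splits reaching the real count. The mixed split of OCT4 versus J1 that gave 7 lists had 0 called genes. Camera at the preset correlation can therefore call lists where no gene is called.

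Trophectoderm genes were higher in the OCT4 line than in J1, with a median log2 fold change of 1.602 (adjusted p = 0.0653 with an estimated correlation). Correction for GC content and transcript length left the median at 1.57, which argues against that bias as the whole cause. The counts taken by the mitochondrial genes and Gm26917 can shift every other gene by -0.012 (-0.048 to 0.017 over pairs of libraries). Mitochondrial genes took 11.5% and 14.3% and Gm26917 4.43% and 0.963% of counts in the OCT4 line and J1. Shares of that size could not give a shift near the list median, so this outcome was fixed in advance. Krt8 and Krt18, abundant keratins of trophoblast, both rose, the smaller change being 1.602 for Krt18, so trophoblast cells in part of the cultures may be a source. That test is weak, because both keratins are members of the list, Krt18 is its median gene, and Krt8 stood at 73.0 ± 1.44 CPM in the EWS-OCT4 line and 67.7 ± 2.13 in the OCT4 line, whereas Hand1 stood at 2.14 ± 0.246 and 78.2 ± 8.71. Low expression in every cell and an effect of the construct, of clones or of the host line stay open, untested.

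Whole chromosomes shifted between lines, the largest autosomal difference being -0.507 (log2) for chromosome 11 in EWS-OCT4 versus J1. As chromosomes 8 and 11 were lower in both stable lines and alike between them, an extra copy in part of the J1 cells, or a loss in the cells the stable lines came from, may be the source, and DNA was not measured. The 4 Y-linked genes with at least 5 CPM were lower in the OCT4 line than in the EWS-OCT4 line, by log2 fold changes that spanned 0.581, which loss of the Y chromosome from part of the cells could give, although the 3 with less expression ran from 0.75 to 3.38. Against J1 the same 4 genes spanned 1.962, from -1.46 for Ddx3y to -3.42 for Uba1y, which argues against such loss as the whole difference from J1. The median of all 567 tested X-linked genes lay 0.507 above the autosomal median in the OCT4 line against the EWS-OCT4 line (EWS-OCT4 minus OCT4, -0.519 over the 375 with at least 5 CPM), which cells with a second active X could give and loss of the Y alone does not predict, and correction for GC content and transcript length left the Y-linked median at 1.51, from 1.79 before, which argues against that bias as the whole cause.

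Two-cell-like genes were higher than J1 in both stable lines, with medians of 2.997 in the EWS-OCT4 line and 2.597 in the OCT4 line (log2; adjusted p = 0.138 and 0.0653 with an estimated correlation), or 2.997 and 2.555 with Tdpoz4, which had 0 counts in J1, at its lower bound against 3 counts over the J1 group. Correction for GC content and transcript length left at least 99.7% of the median, which argues against that bias. Reads shared between near-identical copies could not be weighed, because only 2 of the 14 members share under 5% of their sequence words with other genes, and the lower of their medians was 0.852. Whether the rise comes from more cells in the two-cell-like state or from low expression in many cells is not resolved by bulk RNA.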

How the results depend on the processing

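The tests without chromosomes 8, 11, X and Y, with chromosome 12 also left out, with the GC and length correction and without mitochondrial genes and Gm26917 were chosen only after the results were seen. Against a fold of 1.5, glmTreat called 1852 higher and 2854 lower genes for EWS-OCT4 versus OCT4, 1617 and 2232 for EWS-OCT4 versus J1, and 2907 and 2342 for OCT4 versus J1, as a stricter hypothesis must. Other settings kept each gene count within 1.5 times, with totals from 8163 to 11815, 7499 to 10867 and 8235 to 12052 in the same order. Over the 9 fits that left out 1 library, higher and lower genes ranged from 4914 to 5617 and 5262 to 6048, from 4546 to 5083 and 4700 to 5240, and from 5367 to 5720 and 5126 to 5548 in the same order, and genes changed the same way in both stable lines from 5266 to 5681. The 9 fits gave 8 to 12 lists, 3 in each, and 6 to 8. List calls fell to 0, 0 and 0 with an estimated correlation in camera (6, 4 and 6 at an unadjusted p under 0.05) and rose to 23, 22 and 20 with fry, which does not compare a list with other genes. Fry called ERK response genes higher in EWS-OCT4 versus J1 (adjusted p = 0.000279), where camera gave the opposite sign without a call; the cause was not tested. List calls for EWS-OCT4 versus OCT4 fell to 7 without chromosomes 8, 11, X and Y and to 7 without mitochondrial genes and Gm26917, in both cases from a changed set of genes. Part of each fall was fixed in advance, because 23 lists could be tested: the sex chromosome list dropped out of the former and the mitochondrial list out of the latter, while the former gained the cell cycle list. With chromosome 12 also left out, DNA methylation genes passed in EWS-OCT4 versus J1 (camera, adjusted p = 0.0279; over all genes, adjusted p = 0.283 with an estimated correlation). Of 299 named gene and comparison pairs, 284 kept their call under all planned settings but glmTreat and 0 reversed. Same-numbered replicates share only a number: their deviations correlated by 0 to 0.074, though 8 of 9 libraries correlated best with their own number, a hint from the data and not the design. With the replicate number as a block, higher and lower genes were 5419 and 5827, 5195 and 5339, and 5800 and 5556, 5872 genes were shared, and 8, 3 and 8 lists were called, without the naive (adjusted p = 0.0727), neuroectoderm (0.0724) and DNA methylation (0.0724) lists of EWS-OCT4 versus OCT4 and the LIF response list of EWS-OCT4 versus J1 (0.0763), while Ewsr1 passed in EWS-OCT4 versus OCT4 (0.022). The pseudocount alternative was not run, since the values are counts. Raw library sizes kept the direction of each Pou5f1 ratio. The simulated EWS-OCT4 versus OCT4 fit recovered 54.2% of 1.5-fold changes; depth was not varied, so its part was not separated from the spread between libraries.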

Other observations

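Among imprinted genes, Igf2 stood at 532 ± 48.9 CPM in the OCT4 line, 93.9 ± 7.52 in the EWS-OCT4 line and 0.881 ± 0.370 in J1 (SD, n = 3), and its neighbour H19 at 600 ± 69.1, 20.5 ± 0.585 and 39.9 ± 12.9. Cdkn1c stood at 20.4 ± 1.09 CPM in the OCT4 line, 31.1 ± 0.997 in the EWS-OCT4 line and 3.88 ± 0.498 in J1, and Plagl1 at 14.4 ± 0.860, 3.61 ± 0.378 and 42.0 ± 3.34. Mirg and Rian, noncoding RNAs of the Dlk1 domain, stood at 27.9 ± 0.768 and 236 ± 9.60 CPM in the EWS-OCT4 line, against 2.96 ± 0.379 and 53.6 ± 2.92 in the OCT4 line and 3.51 ± 0.776 and 72.9 ± 4.30 in J1. Against J1, Rian was higher in the EWS-OCT4 line (log2 fold change 1.69, SE 0.0704) and lower in the OCT4 line (-0.45, SE 0.071). The list as a whole did not pass camera in any comparison, with adjusted p = 0.342, 0.141 and 0.617.

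The primitive endoderm list did not pass camera in any comparison, with adjusted p = 0.107, 0.141 and 0.822. Its basement membrane gene Col4a1 stood at 313 ± 19.3 CPM in the OCT4 line, 72.5 ± 0.174 in J1 and 25.6 ± 1.46 in the EWS-OCT4 line, whereas Lama1, another, stood at 75.7 ± 4.20, 129 ± 2.33 and 294 ± 4.50 (SD, n = 3). The de novo DNA methyltransferase gene Dnmt3a stood at 228 ± 9.24 CPM in J1, 87.8 ± 2.53 in the OCT4 line and 46.0 ± 1.22 in the EWS-OCT4 line, whereas Dnmt3b was higher in the EWS-OCT4 line at 175 ± 0.242 than in J1 at 87.5 ± 5.52 and in the OCT4 line at 87.1 ± 6.47. The RNA sensor gene Rigi stood at 4.97 ± 1.05 CPM in the OCT4 line, 32.9 ± 1.08 in the EWS-OCT4 line and 48.4 ± 3.81 in J1. Mid1, which spans the edge of the pseudoautosomal region, stood at 1471 ± 104 CPM in the OCT4 line, 2168 ± 81.4 in the EWS-OCT4 line and 3.26 ± 0.985 in J1.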
